A study of Homo sapiens with 10 samples.

How the data were processed

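PANC-1 cells, an established line from a human pancreatic carcinoma, were profiled by RNA sequencing in 10 libraries. The labels put 5 libraries in the LY group (20 µM LY, 24 h) and 5 in the DMSO group. LY stands for lycorine, an alkaloid of Amaryllidaceae plants, per the series title. Control columns of the table are named NC-1 to NC-5, a name that occurs in no sample title. They were assigned to the DMSO group as a whole, and their numbers were not tied to single samples. The series text speaks of 4 samples per group and the labels list 5, so all 10 columns were used. RNA was extracted with Trizol per the series text and with an RNeasy kit per the labels. Library construction used the Hieff NGS MaxUp dual-mode mRNA kit, per the labels.

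The deposited table holds TPM, transcript abundances normalised for transcript length and library total, which the authors computed from the reads, with 1 column per library. Every column sums to nearly the same total over the listed genes (999932 to 999967), and no scaling across libraries is stated. Genome builds GRCm38, mm10 and hg38 are listed in the labels without their roles, whereas the gene IDs are human Ensembl IDs. The aligner, the counting tool, the annotation and the handling of overlapping genes are not given in the sources used here. TPM keeps no read totals, so the depth of each library is unknown and no counting interval can be given. Of 20263 listed genes, 20148 carried a symbol in the table and 76 more were named from GENCODE release 29, which left 39 unnamed. Positions on hg38 (20224 genes), transcript length, GC content and 3' UTR sequences came from the same release. The table holds 19722 protein-coding genes, and 4217 genes were at 0 in every library. No column was left out.

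Tests used R 4.3.3 with limma 3.58.1. Genes with a TPM of at least 1 in at least 5 of the 10 libraries were kept (11663 genes), whatever their group. A linear model with the group as its only term was fitted to log2(TPM + 1), with a mean-variance trend in the moderation (limma-trend). Benjamini-Hochberg adjustment covered all kept genes, and an adjusted p under 0.05 counted as a change. Fold changes are LY over DMSO. Data of 11663 genes were simulated with planted changes in 50 genes per size. The fit recovered 10% at 1.25-fold, 46% at 1.5-fold, 78% at 2-fold and 96% at 4-fold. It made 8 false calls among the genes without a planted change. Far fewer genes changed in the simulation than in the data, which makes the adjusted threshold stricter. These rates may therefore understate recovery in the data. All p-values measure the spread between these samples, since no source says whether the 5 libraries of a group came from separate cultures.

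Before the data were examined, 40 gene lists, the genes to name, the tests and most alternative settings were chosen. The 37 lists with at least 5 kept members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation, and limma's fry, stand beside it. The directional p of fry asks whether members move on balance one way, its mixed p asks whether they change in either direction, and neither compares a list with other genes. A score per library (mean of the members less the mean of all genes) was compared by a two-sided exact permutation test over 252 assignments, whose smallest p is 0.0079; this test was added after the data were seen. List members DDX58 and H3C2 are not in the table. Named genes follow a rule. It takes the 12 largest increases and the 12 largest decreases among changed genes with a mean TPM of at least 10 in the higher group and no overlap between groups. It adds 2 changed members per list with the largest change, the changed member with the largest change the opposite way, and 11 genes fixed by name. A list with no changed member gives its most abundant tested member. Together the rule names 131 genes. Of these genes and the 37 tested lists, 2 genes and 1 list count in the totals but are not reported here. Markers of acinar, endocrine, leukocyte, endothelial and fibroblast cells were among the lists.

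Composition of the libraries was compared on 3 measures by two-sided exact permutation tests, adjusted over the 3. The alternative settings chosen at that time were pseudocounts of 0.1 and 0.5, no filter and a stricter filter at a TPM of 5, median-ratio, quantile and upper-quartile scaling, removal of the mitochondrial and 50 most abundant genes, limma without trend, with robust moderation or with array weights, an exact Wilcoxon test, and leaving out each library or each of 25 pairs of 1 LY and 1 DMSO library. Alternatives chosen after seeing the data were leaving out NC-2 with median-ratio scaling, leaving out NC-2, LY-1 and LY-2 together, removing only the mitochondrial genes, the list scores, and an estimated correlation without NC-2. A library's value was marked as apart from its group by Dixon's ratio above 0.71. The groups were also redrawn in 100 of the 126 possible splits into 5 and 5 libraries, the real one included. Bootstrap intervals (95%) and permutation tests of gene sets used 10000 draws, and the bootstraps of the AU-rich test and the permutations within its GC strata 1000. Genes that overlap another gene on the genome or have close paralogs (histones, metallothioneins, HSPA1A and HSPA1B) carry values that depend on an unknown assignment of shared reads.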

Results

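Transcript levels were measured by RNA sequencing in PANC-1 cells, a human pancreatic carcinoma line. Cells received 20 µM LY (lycorine, known to inhibit protein synthesis on ribosomes) or its vehicle DMSO for 24 h, with 5 libraries per group. The series title asks how lycorine affects these cells, and LY against DMSO is the 1 comparison the labels give. Values are deposited TPM, given as the mean ± SD over 5 libraries per group, and fold changes are LY over DMSO on the log2 scale ± SE of the limma fit. The depth of the libraries is unknown. Positions refer to hg38.

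Mitochondrially encoded genes took 9.44 ± 3.63% of all TPM in LY and 18.2 ± 10.8% in DMSO (difference -8.78 points, two-sided exact permutation p = 0.0556, adjusted p = 0.0556). Control library NC-2 held 37.5%, against 12.2% to 14.1% in the other 4 controls, and without NC-2 the difference was -3.96 points (adjusted p = 0.103, exact permutation). In LY the mitochondrial share ran from 6.43% to 14.9%. The 50 most abundant genes took a smaller share in LY (23.1 ± 2.27% against 32.6 ± 8.29%, difference -9.49 points, exact permutation p = 0.0079, adjusted p = 0.0238), and without NC-2 this difference was -5.79 points (adjusted p = 0.0238). The 50 were taken from all genes, mitochondrially encoded ones included, so this share is not independent of the mitochondrial share. NC-2 was highest in both, with 47.4% in its 50 most abundant genes. A share without mitochondrial genes was not tested. Genes at a TPM of at least 1 numbered 11386 ± 35.1 in LY and 11649 ± 176 in DMSO (difference -263, exact permutation p = 0.0476, adjusted p = 0.0556), and without NC-2 the difference was -340.2 (adjusted p = 0.0238). A principal component analysis of log2(TPM + 1) put the groups on opposite sides of the first component, which held 73.2% of the variance. The second, with 11.5%, set NC-2 at 49.5 and the other controls between -12.0 and -8.37. Spearman's correlation of NC-2 with its own group, across genes, had a median of 0.962, against 0.982 to 0.986 for the other 9 libraries. Genes are not independent replicates in such a correlation.

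**Figure D1:**
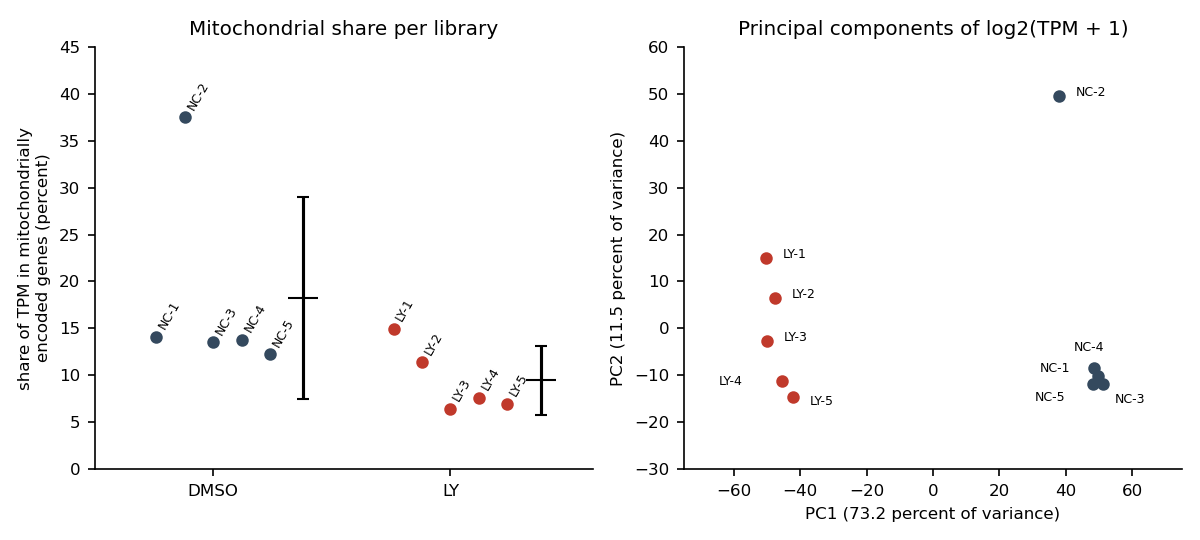
Share of TPM in mitochondrially encoded genes per library (percent) and the first against the second principal component of log2(TPM + 1), each point a library of the LY or DMSO group. NC-2 holds 37.5% mitochondrial TPM, and the first component (73.2% of variance) separates the groups.

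LY-treated cells had higher transcript levels of nucleolar ribosome assembly factors, of YAP/TEAD targets and of anti-apoptotic genes, and lower levels of DNA replication genes and interferon-stimulated genes, by a list test (limma's camera) at a preset inter-gene correlation. None of these lists passed with an estimated correlation, and the anti-apoptotic list was also lost with a minimum TPM of 5. Of 40 ribosome biogenesis genes 36 rose, with RRP12 going from 9.80 to 52.9 TPM, whereas 34 of 46 DNA replication genes fell. SERPINA3, an acute-phase protease inhibitor, dropped from 490.1 to 6.12 TPM, and IDH1, the cytosolic isocitrate dehydrogenase, from 66.2 to 1.69 TPM. TNFRSF12A, the receptor of the cytokine TWEAK, rose from 105 to 1349.5 TPM, and CCN1, a secreted matrix protein and YAP target, from 101 to 967 TPM (n = 5 per group). In all, 7538 of 11663 tested genes (64.6%) changed in the limma fit, 4639 of them up and 2899 down, and 2581 changed at least 2-fold. LY and DMSO values did not overlap in 5761 genes (49.4%), where chance gives 0.794%. The split by direction depended on scaling. It was 3853 up and 3863 down with median-ratio scaling, 4055 and 3694 with quantile normalization, 3346 and 4371 with upper-quartile scaling, 3640 and 4003 after removal of the mitochondrial and 50 most abundant genes, and 4094 and 4147 without NC-2 and with median-ratio scaling. The median log2 fold change of all tested genes was 0.17 as deposited, 0.012 with median-ratio, 0.051 with quantile and -0.080 with upper-quartile scaling. Changes of lists are therefore also given relative to the median of all genes, called the relative median.

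Among the largest increases, ALOXE3 (ENSG00000179148, chromosome 17, 8095900 to 8119047), a lipoxygenase known from the skin barrier, reached 63 ± 15.6 TPM in LY against 2.23 ± 0.374 in DMSO (log2 fold change 4.28 ± 0.16, adjusted p = 7.42e-09). TMEM40, a membrane protein, rose from 5.28 to 93.8 TPM (log2 fold change 3.93 ± 0.13). S100A2, a calcium-binding protein, measured 213 ± 48.6 TPM in LY against 14.4 ± 5.61 in DMSO (log2 fold change 3.88 ± 0.29). ADM, which encodes the vasodilator adrenomedullin, rose from 9.86 to 119.7 TPM, and the tumour suppressor RASSF1 from 20.0 to 224 TPM. The complement regulator CD55 went from 6.03 to 72.5 TPM, and the interleukin 6 receptor gene IL6R from 1.18 to 17.8 TPM. GADD45A, a stress-induced gene of growth arrest, measured 467 ± 142 TPM in LY against 49 ± 13.4 in DMSO (log2 fold change 3.21 ± 0.24). TNFRSF12A (3.69 ± 0.19) overlaps CLDN6 on the genome, and APOLD1 (3.14 ± 0.50) overlaps DDX47. TOMM6, a subunit of the mitochondrial import channel that overlaps USP49, measured 275 ± 36.5 TPM in LY against 44.6 ± 52.7 in DMSO. NC-2 held 138 TPM of TOMM6 and the other controls 13.1 to 34.1, and the log2 fold change went from 3.16 to 3.71 without NC-2.

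SERPINA3 (ENSG00000196136, chromosome 14, 94612377 to 94624055) had the largest decrease, with 6.12 ± 2.47 TPM in LY against 490.1 ± 183 in DMSO (log2 fold change -6.07 ± 0.33, adjusted p = 4.08e-08); it overlaps an unnamed gene. IDH1 (ENSG00000138413, chromosome 2, 208236227 to 208266074) measured 1.69 ± 0.328 TPM in LY against 66.2 ± 9.82 in DMSO (log2 fold change -4.64 ± 0.13, adjusted p = 1.82e-09). SECTM1, a secreted and membrane protein, fell from 53.9 to 1.40 TPM (log2 fold change -4.39 ± 0.29). LRRC45, a centrosomal protein that overlaps CENPX, fell from 30.9 to 0.514 TPM. LGALS3BP, a secreted glycoprotein that binds galectins, measured 15.9 ± 1.28 TPM in LY against 221 ± 57 in DMSO (log2 fold change -3.68 ± 0.16). Keratin 15 (KRT15) fell from 29.8 to 1.07 TPM, and ASB9, a substrate adaptor of a ubiquitin ligase, from 30.3 to 1.15 TPM. The calcium channel subunit CACNG4 fell from 29.5 to 1.33 TPM, the glycosyltransferase B4GAT1 from 19.3 to 0.617 TPM and the lysosomal ribonuclease RNASET2 from 19 to 0.992 TPM. The membrane scaffold genes EPB41L1 (-3.42 ± 0.17) and MPP2 (-3.16 ± 0.16) complete the 12 largest decreases. Among tested genes, TMEM37 and TRIM34 were listed at 0 in all 5 LY libraries, with 3.0 ± 0.574 and 1.66 ± 0.531 TPM in DMSO; both were chosen after their values were seen.

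**Figure D2:**
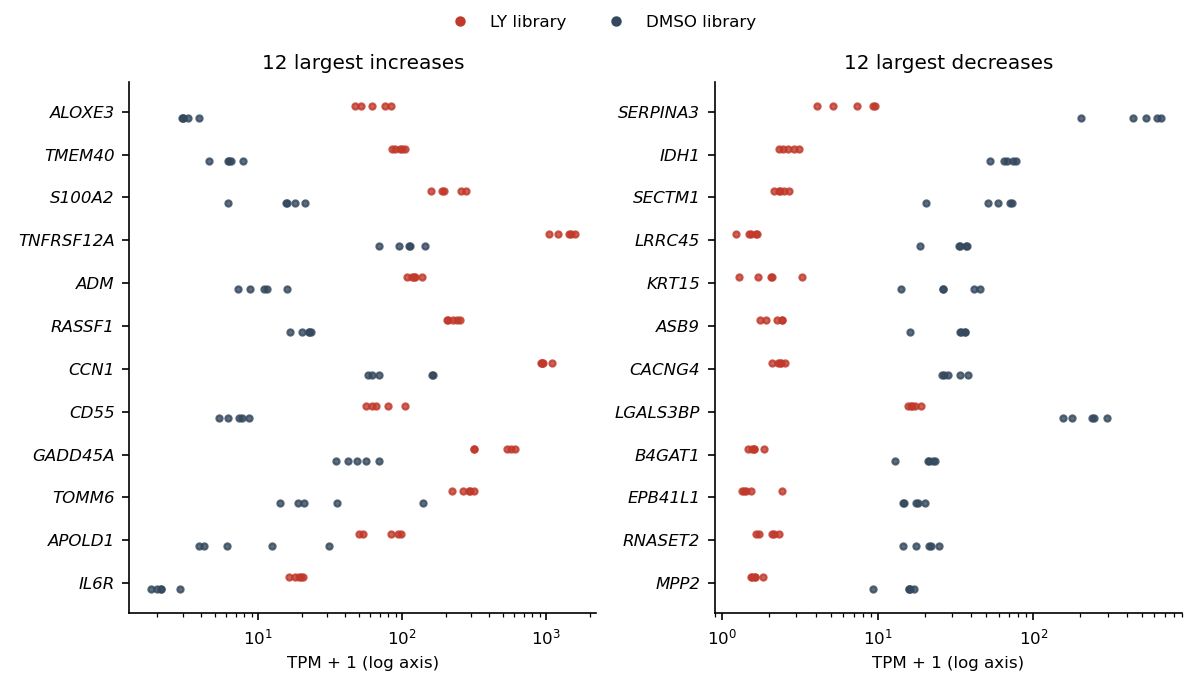
TPM + 1 on a log axis in each LY and DMSO library for the 12 genes with the largest increase and the 12 with the largest decrease. Points are single libraries, and LY and DMSO values do not overlap in any of the 24 genes, as the rule that chose them required.

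Counts of changed members, when adjusted over the list alone, equalled those over all genes unless both are given. Member counts are as deposited, and under median-ratio, quantile or upper-quartile scaling more members fell in most lists. Camera at the preset correlation called 11 of 37 lists and with an estimated correlation 0 (1 list at an unadjusted p under 0.05). Estimated correlations were 0.236 for ribosome biogenesis, 0.307 for G1/S and 0.358 for interferon-stimulated genes, against the preset 0.01. The adjusted p-values of camera at the preset correlation may therefore be too small. Fry called 21 lists by its directional test and 35 by its mixed test, all but the cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation. Scores of 25 lists did not overlap between the 5 LY and 5 DMSO libraries, and 27 lists passed the exact permutation test of these scores. This separation says little about a single list, since 49.4% of all tested genes did not overlap either. Lists that camera did not call, such as Notch and Wnt, separated as well. Genes of ribosome biogenesis and the nucleolus, which build ribosomal subunits, had the largest median of the 37 tested lists (log2 fold change 1.19, relative median 1.03). By mean log2 fold change the YAP/TEAD list was higher (1.26 against 1.11). Of 40 tested ribosome biogenesis genes 36 rose and 4 did not pass. The ribosome biogenesis list passed camera (adjusted p = 1.33e-08, but 0.831 with an estimated correlation). RRP12, a factor of subunit maturation, measured 52.9 ± 10.4 TPM in LY against 9.80 ± 1.10 in DMSO (log2 fold change 2.31 ± 0.13), and the helicase DDX10 rose from 51.4 to 232 TPM. Of the translation factors, 22 of 32 tested members rose, 4 fell and 6 did not pass (relative median 0.50, camera adjusted p = 0.0192; adjusted p = 0.839 with an estimated correlation). EIF5 (1.65 ± 0.13) and EIF3A (1.59 ± 0.10), both of translation initiation, rose, and EIF4EBP1, an inhibitor of cap-dependent initiation, fell (-0.82 ± 0.16).

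Aminoacyl-tRNA synthetases did not pass as a list: 10 of 20 tested members rose, 4 fell and 6 did not pass (camera adjusted p = 0.289), and their relative median of 0.069 turned to -0.080 with quantile normalization. Both phenylalanine enzyme subunits, FARSB (1.41 ± 0.086) and FARSA (1.26 ± 0.11), rose, and the glutamine enzyme QARS1 fell (-1.19 ± 0.16). Of the cytosolic ribosomal proteins, 4 of 46 tested members rose and 42 did not pass, and adjusted over the list alone 3 rose (camera adjusted p = 0.76). RPL10A (0.92 ± 0.24) and RPL24 (0.73 ± 0.11) rose. Their median was 0.061 and their relative median -0.11 (0 with quantile normalization). Without NC-2, the control with 37.5% mitochondrial TPM, and with median-ratio scaling 3 rose and 21 fell.

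**Figure D3:**
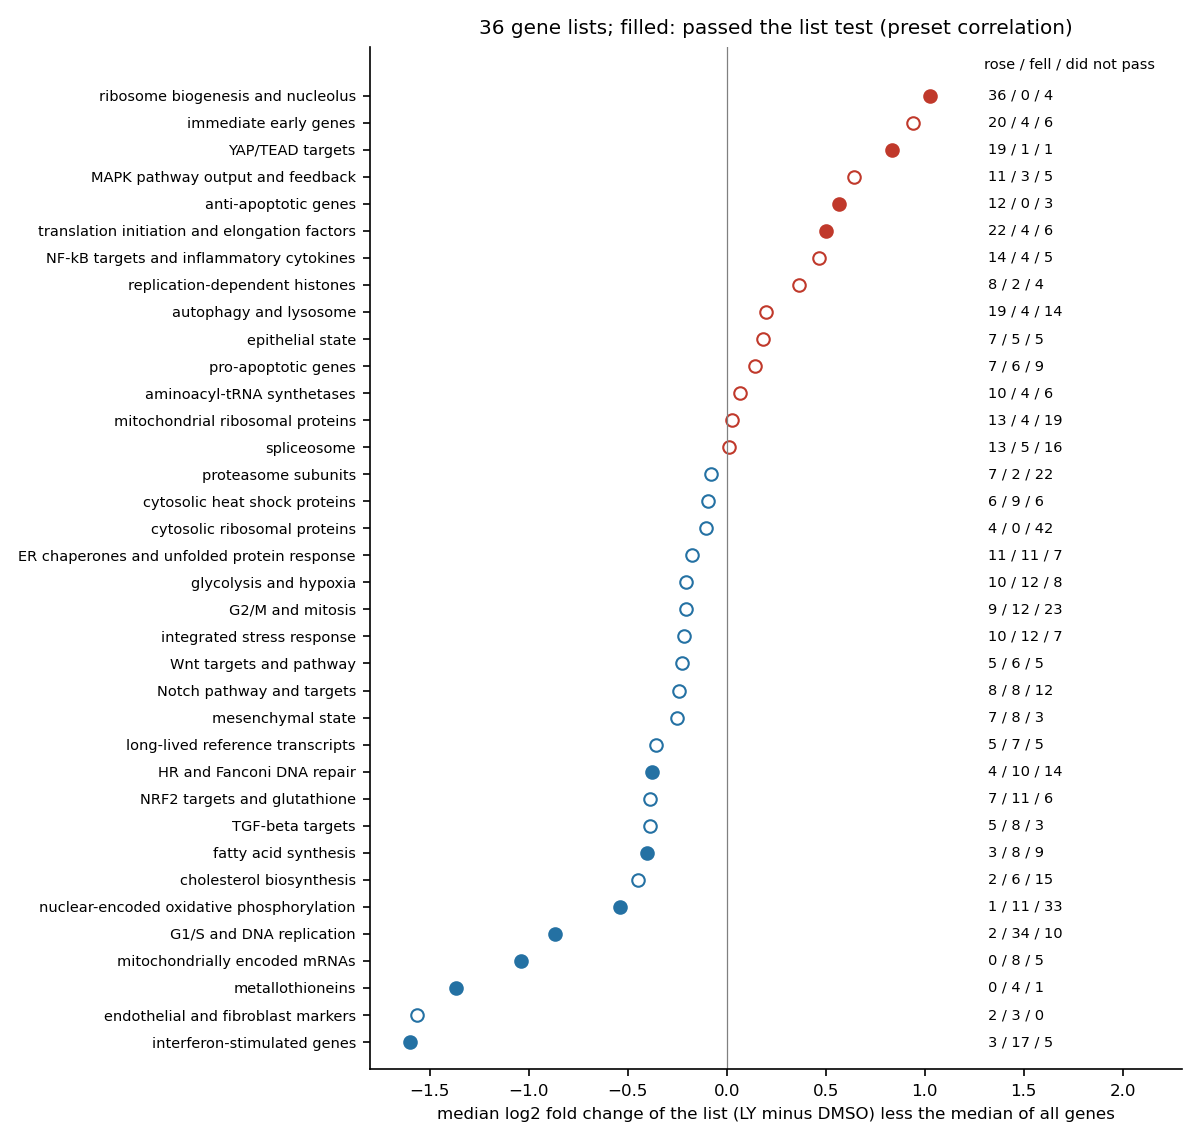
Median log2 fold change of 36 tested lists less the median of all genes (x axis), with the members that rose, fell or did not pass; filled points passed camera at the preset correlation (11 lists), and none passed with an estimated correlation. Medians run from -1.60 (interferon-stimulated genes) to 1.03 (ribosome biogenesis), and those of the aminoacyl-tRNA synthetases, the mitochondrial ribosomal proteins, the spliceosome and the cytosolic ribosomal proteins change sign or reach 0 under at least 1 other scaling.

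Genes of the G1/S transition and DNA replication were lower in LY: 2 of 46 tested members rose, 34 fell and 10 did not pass, and adjusted over the list alone 2 rose and 35 fell (relative median -0.87). The list passed camera (adjusted p = 5.74e-10; adjusted p = 0.831 with an estimated correlation). DNA ligase LIG1 measured 14.4 ± 1.22 TPM in LY against 57.6 ± 9.55 in DMSO (log2 fold change -1.92 ± 0.12), and GINS2, a subunit of the replicative helicase, fell from 55.5 to 15 TPM. CDC25A, a phosphatase that activates cyclin-dependent kinases, rose (0.74 ± 0.15). Of the homologous recombination and Fanconi genes, 4 of 28 tested members rose, 10 fell and 14 did not pass (relative median -0.38, camera adjusted p = 0.0301; adjusted p = 0.839 with an estimated correlation). Without NC-2 this list did not pass (camera adjusted p = 0.0673). RAD54L (-1.52 ± 0.16) and EME1 (-1.18 ± 0.15) fell, and PALB2 rose (0.65 ± 0.12). The G2/M and mitosis list did not pass (camera adjusted p = 0.289): 9 of 44 tested members rose, 12 fell and 23 did not pass, with 9 up and 11 down adjusted over the list alone and as deposited a median of -0.041, a relative median of -0.21 and a mean of 0.0031. Its counts were 7 up and 21 down with median-ratio, 5 and 23 with quantile and 5 and 24 with upper-quartile scaling. The mitotic genes HMMR (1.18 ± 0.15) and CENPE (0.99 ± 0.18) rose and the cyclin CCNA2 fell (-0.67 ± 0.10). With quantile normalization the G2/M list passed, downward (camera adjusted p = 0.0218), but not with median-ratio (0.168) or upper-quartile scaling (0.114), nor as deposited with an estimated correlation (0.872).

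AEN, a nuclease of apoptosis, rose from 34.6 to 140.0 TPM, and the mitochondrial reductase FDXR fell (-0.73 ± 0.17). Of the replication-dependent histones, whose paralogs share much sequence, 8 of 14 tested members rose, 2 fell and 4 did not pass (relative median 0.37, camera adjusted p = 0.235). H2BC12 (1.69 ± 0.16) and H2BC21 (1.33 ± 0.14) rose and H2AC20 fell (-0.75 ± 0.12).

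Stress-response lists went both ways. Of the ATF4 targets of the integrated stress response, 10 of 29 tested members rose, 12 fell and 7 did not pass, and adjusted over the list alone 12 rose and 12 fell (relative median -0.22, camera adjusted p = 0.403). PPP1R15A, a phosphatase subunit that restores translation, rose from 86 to 474 TPM, whereas the serine synthesis enzyme PHGDH (-2.85 ± 0.25) and the mTORC1 inhibitor DDIT4 (-2.84 ± 0.27) fell. Of the endoplasmic reticulum chaperones and unfolded protein response genes, 11 of 29 tested members rose, 11 fell and 7 did not pass (relative median -0.17, camera adjusted p = 0.482). The stress sensor ERN1 rose (1.50 ± 0.12) and SDF2L1 fell (-1.86 ± 0.34). Among cytosolic heat shock proteins, 6 of 21 tested members rose, 9 fell and 6 did not pass (camera adjusted p = 0.208), with a median of 0.072, a relative median of -0.10 and a mean of -0.39. HSPA1A (-2.88 ± 0.12) and HSPA1B (-2.89 ± 0.13), inducible chaperones with nearly identical sequences, fell, and the co-chaperone DNAJB6 rose (1.09 ± 0.15). Metallothioneins, small proteins that bind metals, were lower: 4 of 5 tested members fell and 1 did not pass (relative median -1.37, camera adjusted p = 0.0126; adjusted p = 0.839 with an estimated correlation). MT1E fell from 873 to 303 TPM and MT1M from 21 to 6.95 TPM.

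NRF2 targets and glutathione genes did not pass as a list (camera adjusted p = 0.224, relative median -0.39): 7 of 24 tested members rose, 11 fell and 6 did not pass. OSGIN1 rose from 19.1 to 149 TPM and the thioredoxin reductase TXNRD1 from 685 to 2192 TPM, whereas the quinone reductase NQO1 fell from 442 to 174 TPM. Of the autophagy and lysosome genes, 19 of 37 tested members rose, 4 fell and 14 did not pass, and adjusted over the list alone 19 rose and 3 fell (relative median 0.20, camera adjusted p = 0.224). Counts were 18 up and 10 down with median-ratio, 17 and 11 with quantile and 15 and 10 with upper-quartile scaling. MAP1LC3A (2.09 ± 0.20) and GABARAPL1 (1.66 ± 0.33), both of the autophagosome membrane, rose, and the lysosomal protease CTSB fell (-1.65 ± 0.26). Of the proteasome subunits, 7 of 31 tested members rose, 2 fell and 22 did not pass, with 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.991). Their median was 0.090 and their relative median -0.078, and without NC-2, the library high in mitochondrial TPM, and with median-ratio scaling 6 rose and 12 fell. PSMD6 (0.90 ± 0.082) and PSMC4 (0.81 ± 0.14) rose and PSMD1 fell (-0.64 ± 0.11). For the spliceosome, 13 of 34 tested members rose, 5 fell and 16 did not pass (camera adjusted p = 0.629), and the relative median of 0.013 turned negative under median-ratio, quantile and upper-quartile scaling. Counts were 8 up and 7 down with median-ratio, 5 and 10 with quantile and 5 and 10 with upper-quartile scaling. SNRPF fell (-1.71 ± 0.22) and SF3B4 rose (1.25 ± 0.16).

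Interferon-stimulated genes were lower in LY: 3 of 25 tested members rose, 17 fell and 5 did not pass (median log2 fold change -1.43, relative median -1.60). This list passed camera (adjusted p = 9.24e-06; adjusted p = 0.833 with an estimated correlation). IFI6 fell from 18 to 1.91 TPM, and OAS3, a sensor of double-stranded RNA, measured 2.97 ± 0.496 TPM in LY against 23.4 ± 3.24 in DMSO (log2 fold change -2.62 ± 0.13). IFIT5 rose (1.49 ± 0.093), as did IFIT2 (1.39 ± 0.17) and ISG20 (1.31 ± 0.25), the latter pair chosen after their values were seen. YAP/TEAD targets, controlled by the Hippo pathway, were higher: 19 of 21 tested members rose, 1 fell and 1 did not pass (relative median 0.83, camera adjusted p = 9.11e-05; adjusted p = 0.54 with an estimated correlation). CCN1 measured 967 ± 69.5 TPM in LY against 101 ± 53.8 in DMSO (log2 fold change 3.40 ± 0.29), AMOTL2 rose from 41.1 to 276 TPM, and NT5E fell (-0.42 ± 0.094).

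Of the immediate early genes, 20 of 30 tested members rose, 4 fell and 6 did not pass (relative median 0.94), and the list did not pass (camera adjusted p = 0.0574). IER5L fell from 59.9 to 8.77 TPM while CCN1 had the largest increase. Of the genes of MAPK pathway output and feedback, 11 of 19 tested members rose, 3 fell and 5 did not pass (relative median 0.64, camera adjusted p = 0.0702). PHLDA1 (2.60 ± 0.26) and the AP-1 subunit FOSL1 (2.60 ± 0.24) rose and the transcription factor ETV1 fell (-1.90 ± 0.16). Both lists passed under median-ratio scaling, with a camera adjusted p of 0.0143 for the immediate early genes and 0.0461 for the MAPK list. The MAPK list did not pass with quantile normalization (camera adjusted p = 0.0708). Without NC-2 and otherwise as deposited neither list passed (0.0547 for MAPK and 0.0617 for the immediate early genes). Without NC-2 and with median-ratio scaling both passed (0.0462 for MAPK and 0.0340 for the immediate early genes). With an estimated correlation neither list passed as deposited (both 0.839). The same held without NC-2 and with median-ratio scaling (0.439 for MAPK and 0.676 for the immediate early genes). Of the NF-kB targets and inflammatory cytokines, 14 of 23 tested members rose, 4 fell and 5 did not pass (relative median 0.46, camera adjusted p = 0.235). The cytokine genes IL1A (2.96 ± 0.20) and CXCL8 (2.33 ± 0.27) rose, and the transcription factor IRF1 fell (-1.71 ± 0.22).

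For the Notch pathway, 8 of 28 tested members rose, 8 fell and 12 did not pass (relative median -0.24, camera adjusted p = 0.305). The counts were 4 up and 12 down with median-ratio, 5 and 12 with quantile and 4 and 12 with upper-quartile scaling. LFNG, a glycosyltransferase that modifies Notch, fell from 17 to 1.25 TPM, and the Notch target HES4 rose from 10.9 to 41.8 TPM. For the Wnt list, 5 of 16 tested members rose, 6 fell and 5 did not pass (relative median -0.23, camera adjusted p = 0.289). The receptor FZD2 (-3.06 ± 0.19) and the transcription factor TCF7 (-2.25 ± 0.26) fell, and the co-receptor LRP6 rose (0.82 ± 0.13). Among TGF-beta targets, 5 of 16 tested members rose, 8 fell and 3 did not pass (relative median -0.39, camera adjusted p = 0.211). ID1 fell from 326 to 46.2 TPM and LTBP3 from 42.9 to 6.26 TPM, whereas FSTL3, an activin antagonist, rose from 11 to 61.9 TPM.

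**Figure D4:**
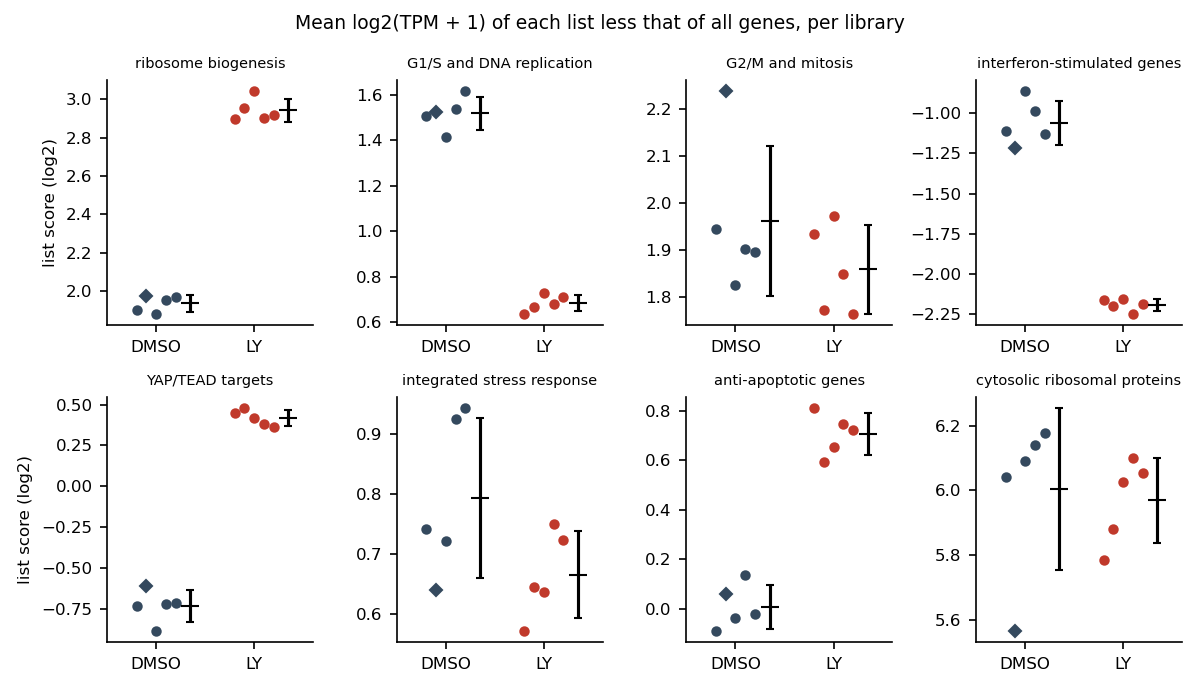
Score of 8 lists in each library (mean log2(TPM + 1) of the members less the mean of all tested genes), with the mean ± SD per group and NC-2 drawn as a diamond. LY and DMSO scores of ribosome biogenesis, G1/S, interferon-stimulated, YAP/TEAD and anti-apoptotic genes do not overlap. Those of the ATF4 targets, G2/M genes and cytosolic ribosomal proteins do. Scores of some lists that camera did not call, such as Notch and Wnt (not drawn), do not overlap either.

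Anti-apoptotic genes were higher: 12 of 15 tested members rose and 3 did not pass (relative median 0.56, camera adjusted p = 0.0205; adjusted p = 0.833 with an estimated correlation). BIRC3 measured 70.9 ± 15.9 TPM in LY against 13.7 ± 1.73 in DMSO (log2 fold change 2.26 ± 0.16) and BIRC2 rose from 24.5 to 111 TPM; both encode inhibitors of apoptosis with ubiquitin ligase activity. With a minimum TPM of 5 this list did not pass (camera adjusted p = 0.0758). MCL1, a short-lived member of the BCL2 family, measured 92.8 ± 8.26 TPM in LY against 113 ± 21.4 in DMSO and did not pass (log2 fold change -0.27 ± 0.13, adjusted p = 0.0928), but it fell with median-ratio scaling (-0.44, adjusted p = 0.00492). Of the pro-apoptotic genes, 7 of 22 tested members rose, 6 fell and 9 did not pass, with a median of 0.31, a relative median of 0.14, a mean of 0.14 and camera's direction down (adjusted p = 0.845). The effector caspase CASP6 fell from 14.1 to 2.80 TPM, and the death receptor TNFRSF10A rose from 21.9 to 71.6 TPM.

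Among mitochondrially encoded mRNAs, 8 of 13 tested members fell and 5 did not pass (relative median -1.04, camera adjusted p = 0.00831; adjusted p = 0.839 with an estimated correlation). MT-ND6 measured 1384 ± 670.0 TPM in LY against 4108 ± 2152 in DMSO and MT-ND5 1893 ± 833 TPM in LY against 5270.4 ± 2996 in DMSO. NC-2 held 10625 TPM of MT-ND5, the other controls 3751 to 4084. The list passed without NC-2 (camera adjusted p = 0.0324, relative median -0.70). Without NC-2, LY-1 and LY-2, the libraries with the highest mitochondrial shares of their groups, all 13 members fell (camera adjusted p = 1.05e-06). Leaving out LY-1 and LY-2 lowers the LY values of the very quantity under test. This setting, chosen after the data were seen, therefore cannot count as support. The mitochondrially encoded list did not pass without NC-2 and with median-ratio scaling (camera adjusted p = 0.0556), with quantile normalization (0.164, relative median -0.37) or with upper-quartile scaling (0.0615). In the exact permutation test of its scores the list did not pass either (adjusted p = 0.0524, 0.111 without NC-2). Of the nuclear-encoded oxidative phosphorylation genes, 1 of 45 tested members rose, 11 fell and 33 did not pass, with 5 down and the single increase lost when adjusted over the list alone (relative median -0.54, camera adjusted p = 0.00831; adjusted p = 0.839 with an estimated correlation). Without NC-2 and with median-ratio scaling 36 fell. ATP5F1A fell from 549 to 306 TPM and NDUFB10 from 148 to 86.4 TPM, and ATP5MC1 rose from 326 to 422 TPM (adjusted p = 0.038), a call lost with median-ratio scaling (adjusted p = 0.0656) and without any single LY library (0.0555 to 0.0698). For the mitochondrial ribosomal proteins, 13 of 36 tested members rose, 4 fell and 19 did not pass, with 11 up and 4 down adjusted over the list alone (camera adjusted p = 0.699). Their relative median of 0.026 turned negative with quantile normalization, and without NC-2 and with median-ratio scaling 11 rose and 10 fell. MRPS30 rose (1.83 ± 0.16) and MRPS34 fell (-1.05 ± 0.12).

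Fatty acid synthesis genes were lower: 3 of 20 tested members rose, 8 fell and 9 did not pass, with 2 up and 8 down adjusted over the list alone (relative median -0.40, camera adjusted p = 0.0223; adjusted p = 0.839 with an estimated correlation). Without NC-2 and with median-ratio scaling 1 member rose and 12 fell. The carboxylase ACACB fell from 10.5 to 0.766 TPM and the desaturase FADS2 from 48 to 13.6 TPM. ACSL4, which activates polyunsaturated fatty acids, rose from 13.1 to 42.4 TPM. For cholesterol biosynthesis, 2 of 23 tested members rose, 6 fell and 15 did not pass (relative median -0.45, camera adjusted p = 0.0597, and 0.839 with an estimated correlation). The list passed with median-ratio (0.0329), quantile (0.0121) and upper-quartile scaling (0.0276) and with a minimum TPM of 5 (0.0302). Without NC-2 and with median-ratio scaling it also passed (camera adjusted p = 0.0195, but 0.322 with an estimated correlation), and 2 rose and 17 fell. ACAT2 (-1.49 ± 0.16) and EBP (-1.18 ± 0.15) fell and CYP51A1 rose (0.89 ± 0.12). Of the glycolysis and hypoxia genes, 10 of 30 tested members rose, 12 fell and 8 did not pass (camera adjusted p = 0.509), with a median of -0.037, a relative median of -0.20 and a mean of 0.11. ADM had the largest increase in this list, and the collagen prolyl hydroxylase P4HA2 fell from 34.6 to 4.67 TPM.

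Of the epithelial state genes, 7 of 17 tested members rose, 5 fell and 5 did not pass (camera adjusted p = 0.897), with a median of 0.35, a relative median of 0.18, a mean of -0.023 and camera's direction down. Keratin 19 (KRT19) fell from 148 to 21 TPM, and the tight junction gene CLDN1 rose from 17.5 to 82.4 TPM. For the mesenchymal state, 7 of 18 tested members rose, 8 fell and 3 did not pass (relative median -0.25, camera adjusted p = 0.289). COL6A1, a collagen chain, fell from 82.1 to 14.3 TPM, and the actin-binding gene TAGLN rose from 9.23 to 31.8 TPM. In the list called long-lived reference transcripts, 5 of 17 tested members rose, 7 fell and 5 did not pass (relative median -0.36, camera adjusted p = 0.235). Half-lives were not measured, so the name of this list does not show that a member is long-lived. Its member TFRC, the transferrin receptor, fell from 171 to 62.1 TPM.

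Markers of other cell types were mostly under the filter. Of 17 acinar markers 1 was tested, CEL, which fell from 2.22 to 1.03 TPM. Of 14 endocrine markers 4 were tested and SCG2 rose (0.25 ± 0.10, adjusted p = 0.0372), a call lost when adjusted over the list alone; its log2 fold change turned negative with quantile and upper-quartile scaling, and the call was lost without LY-1 (adjusted p = 0.0776). SCG2 was at 368 ± 21 TPM in DMSO, while INS, GCG and SST were at 0 in every library. The other tested endocrine markers were PCSK1N (26.5 TPM in DMSO), PAX6 (19.9 TPM) and CHGB (1.12 TPM). Of 20 leukocyte markers 4 were tested, 2 rose and 1 fell. CD68, also a lysosomal protein of other cells, rose from 39.8 to 179 TPM, ITGAM, chosen after its values were seen, rose from 0.566 to 1.62 TPM, and CORO1A fell from 12.5 to 1.91 TPM. Of the endothelial and fibroblast markers, 2 of 5 tested members rose and 3 fell (relative median -1.57, camera adjusted p = 0.289). CDH5 rose from 0.368 to 3.01 TPM, whereas C1S, which overlaps EMG1 and LPCAT3, fell from 4.47 to 0.507 TPM and FBLN1 from 21.1 to 6.21 TPM.

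Genes fixed by name included the transcription factor MYC, which measured 160.1 ± 136 TPM in LY against 46.6 ± 6.18 in DMSO (log2 fold change 1.48 ± 0.35, adjusted p = 0.00288). Library LY-2 held 402 TPM of MYC and the other LY libraries 88.7 to 121, and without LY-2 the log2 fold change was 1.08 (adjusted p = 4.85e-05). Cyclin D1 (CCND1) fell from 95.3 to 45.6 TPM (log2 fold change -1.05 ± 0.10). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 13.5 to 32.3 TPM (log2 fold change 1.29 ± 0.26). The stress transcription factors ATF4 (0.95 ± 0.13) and DDIT3 (1.87 ± 0.39) rose, and DDIT3 overlaps MARS1. NOTCH1 fell (-0.56 ± 0.12), and its target HES1 did not pass (-0.36 ± 0.16, adjusted p = 0.0657). HES1 fell under median-ratio scaling (-0.51, adjusted p = 0.00576). The proliferation marker MKI67 measured 212 ± 26.2 TPM in LY against 169 ± 49.6 in DMSO and did not pass (0.36 ± 0.17, adjusted p = 0.0836), but it rose without NC-2 (0.51, adjusted p = 0.00189). Elongation factor EEF1A1 measured 7696 ± 2085 TPM in LY against 7217 ± 1766 in DMSO and did not pass (log2 fold change 0.077 ± 0.22, adjusted p = 0.777), and its log2 fold change was -0.094 under median-ratio, -0.19 under upper-quartile and 0.58 under quantile scaling.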

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

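The tests of RNA mixing, of the LY effect in single controls, of marked genes after rescaling and of transcript length and GC content in NC-2 were chosen only after the result was seen, in place of earlier forms that left mixing and the bias undecided. Control library NC-2 lay apart from the other 4 DMSO libraries in 31 of 134 values tested per library (3 composition measures and 131 genes), and the other 9 libraries lay apart from their own groups in 0 to 5 values; chance marks about 1 in 20 groups. A higher mitochondrial share alone, diluting all other genes, is argued against, since with mitochondrial genes removed and median-ratio scaling NC-2 was still the outlying library in 86.7% of 2020 genes with an outlying DMSO library. A bias by transcript length or GC content as the whole cause is argued against, since after smoothing on both NC-2 was the outlying library in 79.1% of 1695 such genes, although across genes, which are not independent replicates, its deviation correlated with GC content (Spearman's rho -0.494) and length (0.322), with which the LY effect also correlated (-0.304 and 0.157). RNA of LY-treated cells mixed into NC-2 would shift raised and lowered genes by the same share of the LY change, but the median shares were 0.0322 (0.00438 to 0.0761, 37 genes at least 4-fold higher in LY) and 0.224 (0.127 to 0.276, 96 genes at least 4-fold lower), so mixing is argued against as the whole cause and a small admixture stays open. NC-2 did deviate towards LY: with deviation and LY effect taken against separate controls, rho was 0.351, and 0.241 after length and GC were removed (-0.219 to -0.0800 and -0.162 to -0.0499 for the other 4 controls, whose references include NC-2). No biological explanation was tested, since the design names no difference between controls, and RNA quality of this library stays open as untested.

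In NC-2 the mitochondrial share was 37.5% (12.2% to 14.1% in the other controls), the share of the 50 most abundant genes 47.4% (28.0% to 29.3%) and the number of genes at a TPM of at least 1 was 11340 (11677 to 11765). Genes lower in NC-2 than in the other 4 controls included ASB9 (15.1 TPM against 32.7 to 35.2), ATP5MC1 (204 TPM against 341 to 372), B4GAT1 (11.9 TPM against 20.1 to 22.2), CCND1 (79.8 TPM against 98 to 101), CTSB (146 TPM against 232 to 265), EBP (59.6 TPM against 91 to 102), EIF4EBP1 (146 TPM against 223 to 245), EME1 (11.7 TPM against 18.1 to 20.8) and FDXR (27.5 TPM against 45.9 to 49.2). Lower in NC-2 were also LRRC45 (17.6 TPM against 32.2 to 36.3), MPP2 (8.30 TPM against 14.8 to 16), MRPS34 (129 TPM against 177 to 193), MT1E (528 TPM against 938 to 1006), PHGDH (33.6 TPM against 76.6 to 88.5), PSMC4 (171 TPM against 259 to 282), RPL10A (764 TPM against 1549 to 1841), SDF2L1 (14 TPM against 43.4 to 52.7) and TXNRD1 (542 TPM against 705 to 758). Genes higher in NC-2 were CENPE (33.1 TPM against 17 to 21.5), CLDN1 (22.4 TPM against 15.2 to 17.2), DDX10 (64.2 TPM against 46.1 to 49.9), HMMR (115 TPM against 69.1 to 75.1), MRPS30 (161 TPM against 107 to 114), MT-ND5 (10625 TPM against 3751 to 4084), MT-ND6 (7946 TPM against 2949 to 3397), PHLDA1 (156 TPM against 76 to 90.8), SF3B4 (151 TPM against 113 to 120.5) and TOMM6 (138 TPM against 13.1 to 34.1). These values are as deposited, and the mitochondrial share of NC-2 lowers all its other genes. With mitochondrial genes removed and TPM rescaled, 15 of the 18 genes lower in NC-2 were still below the other controls, MRPS34 and TXNRD1 lay within their range and CCND1 above it (128 TPM against 112 to 118). The 8 nuclear genes higher in NC-2 stayed higher. By the same ratio 13 of these 26 genes still lay apart.

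In the LY group, library LY-2 lay apart from the other 4 in ACACB (0.979 TPM against 0.662 to 0.754), CCN1 (1090.3 TPM against 922 to 952), IFI6 (2.87 TPM against 1.56 to 1.88), MYC (402 TPM against 88.7 to 121) and RRP12 (71.1 TPM against 46.2 to 52.2). Single values apart from the other 4 libraries of a group were CTSB in LY-3 (33.5 TPM against 76.3 to 92.7), EEF1A1 in NC-3 (10306 TPM against 5840.3 to 6849.9), EPB41L1 in LY-5 (1.42 TPM against 0.334 to 0.522), MT1M in LY-4 (9.95 TPM against 5.89 to 6.92) and PSMD6 in NC-5 (84.4 TPM against 78.1 to 79.3).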

How the results depend on the processing

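The settings without NC-2 and median-ratio scaled, without NC-2, LY-1 and LY-2, and with mitochondrial genes removed, the exact permutation of list scores, and the estimated correlation without NC-2 were chosen only after the data were seen. No paired analysis was possible because the control columns carry numbers that no label ties to samples, and the fit with the replicate number as a block was not run. Genes changed by LY numbered 6371 with a minimum TPM of 5 to 8449 with array weights among the settings that kept all libraries, 7147 to 8217 without 1 library and 6696 to 8166 without 1 LY and 1 DMSO library. Genes called in a setting and as deposited had opposite directions in 0 cases in each setting. Upper-quartile scaling shared 6245 of the 7538 changed genes and gave 4371 genes lowered by LY, against 2899. This scaling centres the libraries on their abundant genes and moved the median of all genes from 0.17 to -0.080. Camera called 11 lists, and 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 with an estimated correlation without NC-2 and with median-ratio scaling (4 unadjusted), while fry called 21 (directional) and 35 (mixed) and the exact permutation test of list scores 27. Under settings that kept the preset correlation, camera called 10 to 14 lists. For the 10 most abundant genes the difference in share was -7.55 points (adjusted p = 0.0556, exact permutation), against -9.49 for 50 and -7.03 for 500. Without 1 library, the difference in mitochondrial share ran from -10.3 (without NC-5, adjusted p = 0.0476) to -3.96 points (without NC-2, 0.103) and passed also without LY-1 (0.0357); that in genes at a TPM of at least 1 ran from -340.2 (without NC-2, 0.0238) to -234 (without NC-3, 0.0556), in exact permutation tests. That count also passed without LY-1 (0.0476) and without NC-5 (0.0476).

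Of 131 named genes, 8 crossed the threshold in at least 1 setting, and the cause was not tested. SCG2 (0.25, adjusted p = 0.0372) reversed to -0.0040 with quantile (adjusted p = 0.979) and -0.019 with upper-quartile scaling (0.883), and its adjusted p ranged from 0.00661 to 0.979; it was not called without LY-1, LY-2, LY-3, LY-4, NC-1, NC-3, NC-4 or NC-5 (0.0523 to 0.0925). ATP5MC1 ranged from 0.00655 to 0.275 and was not called without any 1 LY library or NC-4 (0.0503). FDXR and NDUFB10 missed the threshold in the exact Wilcoxon test (both 0.0523), with ranges of 7.84e-06 to 0.0523 and 0.000795 to 0.0808. HES1 passed without NC-2 (adjusted p = 0.00864; range 0.00188 to 0.307), as did MCL1 (0.0245; range 0.00121 to 0.388) and MKI67 (0.00189; range 0.00150 to 0.777). The largest shift of a named log2 fold change without 1 library was 0.54. Of 37 lists, 9 crossed the threshold in at least 1 setting. Among them, the mitochondrially encoded, homologous recombination and anti-apoptotic lists were lost, and the immediate early, MAPK, cholesterol, G2/M and histone lists were gained, all at the preset correlation. Without 1 library, the immediate early list passed without LY-3 (camera adjusted p = 0.0394), NC-4 (0.0232) or NC-5 (0.0314). Its scores were 0.399 in NC-4 and 0.316 in NC-5, against -0.307 to -0.195 in NC-1, NC-2 and NC-3. The cholesterol list passed without LY-5 (0.0493) or NC-2 (0.0222). The homologous recombination list missed the threshold without NC-2 (0.0673). Depth is unknown, so counting error cannot be given. On simulated data, with far fewer changed genes than the real data, 10% of 1.25-fold changes were recovered.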

Other observations

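The families by name stem, the test of transcript length and GC content for the interferon-stimulated list, and the GC strata of the AU-rich test were chosen only after the result was seen. Genes of 131 name stems with at least 10 tested members were compared with camera, and none passed with an estimated correlation (adjusted p = 0.953 for each family named here). The UTP genes, of the nucleolar complex that processes the small ribosomal subunit, rose in 11 of 11 members (median 1.35, 1.09 to 1.27 under the other scalings, camera adjusted p = 3.11e-04). UTP14A went from 62.8 to 270.1 TPM and UTP4 from 125 to 462 TPM; 3 of the 11 also stand in the ribosome biogenesis list. DDX helicases rose in 24 of 34 members and fell in 2 (median 0.57, 0.30 to 0.41 under the other scalings, camera adjusted p = 0.0262), and EIF genes, 23 of which stand in the list of translation factors or other lists, rose in 36 of 52 and fell in 6 (median 0.66, 0.39 to 0.50 under the other scalings, camera adjusted p = 0.0206). Zinc finger genes named ZNF rose in 220 of 412 members and fell in 35 (median 0.42, 0.18 to 0.43 under the other scalings, camera adjusted p = 0.0245). Many of them encode DNA-binding repressors. The families were not corrected for GC content or transcript length, with which the LY effect correlated across genes (Spearman's rho -0.304 and 0.157). Whether such a bias raised the ZNF genes was not tested.

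Collagen genes fell in 10 of 15 tested members and rose in 3 (median -1.55, -1.80 to -1.51 under the other scalings, camera adjusted p = 0.00654); 7 of the 15 also stand in the fixed lists. COL26A1 (-2.51 ± 0.15), COL18A1 (-2.41 ± 0.19) and COL4A2 (-2.32 ± 0.16) fell, whereas COL17A1, a collagen of hemidesmosomes, rose from 62.1 to 233 TPM, as did COL27A1 (1.13 ± 0.11) and COL5A3 (1.08 ± 0.14). Genes of intraflagellar transport (IFT), which serves primary cilia, fell in 10 of 15 members (median -0.78, -1.01 to -0.76 under the other scalings, camera adjusted p = 0.0109); IFT22 fell from 34.2 to 11.2 TPM and IFT122 from 37.1 to 12.9 TPM, and IFT57 rose (0.68 ± 0.091). Septins fell in 5 of 10 members (median -0.63, -0.85 to -0.66 under the other scalings, camera adjusted p = 0.0206), among them SEPTIN5 (-2.24 ± 0.14) and SEPTIN6 (-2.18 ± 0.10), while SEPTIN7 measured 0.19 ± 0.11 and did not pass. All genes in these families were chosen after their values were seen.

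The ribosome biogenesis list was higher in LY, with a median log2 fold change of 1.19 over 40 members. Library scaling as the cause is argued against for the scalings tried, since the median closest to 0 over them, with and without NC-2, was 0.93 (0.93 to 1.05). With all libraries kept, these scalings moved the median of all genes from 0.17 to no lower than -0.080. TPM and these scalings give levels relative to other transcripts of a library, so a change in total RNA per cell was not tested. A bias by transcript length or GC content is argued against, since after regression of all genes on both the median was 1.19 (bootstrap interval 1.06 to 1.39). A response of nucleolar genes to LY, the difference the design names, may underlie the increase, as a hypothesis drawn from the same data with no separate test. Batches cannot be examined, since the labels give none, and the list did not pass with an estimated correlation (adjusted p = 0.831).

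The interferon-stimulated list was lower in LY, with a median log2 fold change of -1.43 over 25 members. Library scaling as the cause is argued against for the scalings tried, since the median closest to 0 over them was -1.25 (-1.66 to -1.25). Here too a change in total RNA per cell was not tested. A bias by transcript length or GC content as the whole cause is argued against, since after regression on both the median was -1.42 (bootstrap interval -1.76 to -0.283), 99.4% of its size (80.9% to 139.5%), and the list still passed camera (adjusted p = 9.11e-06). A test written before the result was seen counted a bias as fitting where this interval reached above -0.3, which it did, but the interval before regression (-1.80 to -0.264) reached above it as well, so that test could not decide and was replaced. A lower interferon response under LY may underlie the decrease, as a hypothesis drawn from the same data with no separate test. IFIT2, IFIT5 and ISG20 rose against it, and the list did not pass with an estimated correlation (adjusted p = 0.833).

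AU-rich elements in 3' UTRs are known to shorten the life of transcripts, and a hypothesis was that transcripts carrying them are higher in LY. Of 11551 tested genes with an annotated 3' UTR (112 had none and were not searched), 2406 held an AU-rich nonamer. Within deciles of 3' UTR length, genes with the nonamer were higher in LY by 0.25 on the log2 scale than genes without it (bootstrap interval 0.21 to 0.30, permutation p = 1e-04, the smallest the permutations can give). The log2 fold change itself correlated with GC content across these genes (Spearman's rho -0.262). Within deciles of GC content the difference was 0.17 (0.14 to 0.21), and within quintiles of UTR length crossed with quintiles of GC content 0.16 (0.12 to 0.20, permutation p = 0.001 for both). The median log2 fold change was 0.10 without a nonamer, 0.38 with 1, 0.45 with 2 and 0.44 with 3 or more. These values fit the hypothesis, with a smaller difference once GC content is held, but measure levels, not decay, and genes are not independent replicates.

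Of 100 of the 126 splits of the 10 libraries into 5 and 5, the real one alone (1 of 100) gave as many changed genes (7538, highest other 1892). The same held for genes changed in one direction (4639 raised and 2899 lowered, against at most 1487 in the larger direction of another split). It held also for genes changed at least 2-fold (2581, highest other 571), so a random grouping can be excluded for these counts. The splits cannot tell an LY effect from a batch or culture difference between the groups. For the number of lists called by camera at the preset correlation (11) a random grouping cannot be excluded. These splits did not test single lists, for which the exact permutation test of list scores stands above (27 lists passed). As many were called in 12 of 100 splits, the real one included. Every other split called lists too, from 3 to 15, and most of these splits had no changed gene. Of the 11 other splits with as many lists, 7 kept 4 of the 5 LY libraries together. Between any 2 libraries, at most 0.00687% of nonzero values were identical, so no column is a copy of another.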
